A study of Homo sapiens with 12 samples.

How the data were processed

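The samples were 12 libraries of MCF10A cells, 3 in each of 4 groups given by the labels. Per the labels' protocols, cells grew in DME/F-12 with supplements and horse serum, RNA was prepared with TRIzol and oligo-dT beads, and libraries were made with a TruSeq kit. FastQC, Trimmomatic, TopHat, SAMtools and HTSeq were used on the GRCh37 build, per the submitters' processing notes, with versions not given in the sources used here. The annotation, the strand setting of the counting and the tool used for normalization and testing were not given in the sources used here, and no gene coordinates are printed.

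The authors deposited 2 tables, one per p53 background. Per the file headers, each holds a mean for the vector line, a mean for the H-Ras line and their common mean. The headers do not say how the values were scaled. That this deposited signal is a mean of read counts divided by size factors set within each table was read from the values, as described next. Each also holds a deposited fold change, which is the ratio of the group means, and a deposited p-value with its adjusted value. Neither table has raw counts or columns for single libraries. The headers of both group columns of the p53 wild-type table carry another number than the table's own name does, and what the number stands for is not given. The columns were taken as the vector and H-Ras groups of the table that the samples' descriptions name.

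Values of single libraries were therefore solved from the group means, and every SD and n = 3 rests on these solved values and not on deposited columns. The means were printed to 15 digits, and the lowest nonzero values of each group took 3 levels, the share of the mean that 1 read of each library is worth. For each gene the whole numbers of reads in the 3 libraries that give the printed mean were searched. All splits were searched for means up to 1000. Above that each library was allowed 0.2 to 2.5 times the group mean, and 0.5 to 1.6 times for means over 20000 or where the wider search found several solutions, with no attempt above 60000. These bounds were adjusted over 3 runs after seeing which means were solved. A unique solution was found for 100.0%, 99.9%, 99.9% and 100.0% of genes above 0 in the p53 wild-type vector, p53 wild-type H-Ras, p53-deleted vector and p53-deleted H-Ras groups, and 0 means attempted had no solution. Of 2000 means per group between 3 and 1000, shifted by a relative amount near 1e-07, 0 were solved. On simulated means up to 20000, 99.9% to 100.0% were solved correctly per group and 0 wrongly. The shifted means did not cover the bounded searches above 1000, and neither check covered means over 20000. The simulated libraries differed modestly, so libraries outside the bounds were hardly tested. Size factors recomputed from the solved reads as medians of ratios matched those from the levels within 0.0352%. Genes without a unique solution, mostly very abundant ones, were left out of the tests that use that group and are given there as the authors' deposited means. HRAS in the p53 wild-type H-Ras group had 2 solutions over the wider bounds and was settled by the narrow ones at 18454, 17583 and 14809.5 normalized counts, the other being 28767, 13304 and 8776. The mean is the same for both, and the SD would be larger for the other.

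Solved libraries held 7735518 to 9693931 reads, and adding the unsolved genes gave estimated totals of 7846960 to 10075600 reads. Libraries were named A, B and C by falling size factor within a group and could not be matched to replicate numbers.

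The design fixed before the data were examined named a count test for raw counts and limma on log2(value + 1) for tables without them, and the latter was used here, with fold changes on that scale, which understates changes of low genes. The choice to apply limma to solved values was made after the tables and the authors' numbers of calls had been seen and before any limma fit was run. Group contrasts were fitted with limma 3.58.1 in R 4.3.3 with a mean-variance trend, on genes with at least 10 normalized counts in at least 3 libraries of the fit, and Benjamini-Hochberg adjusted p under 0.05 counted as called, two-sided. The p53 wild-type and p53-deleted comparisons used the 6 libraries of their table, and the difference between backgrounds was an interaction contrast over the 12 libraries. The comparison of the vector lines was to be tested on raw counts of both tables. It is an added analysis on solved reads with median-of-ratios factors over the 12 libraries. The agreement of the H-Ras responses was set against the overlap of independent lists. Python 3.11.15 with NumPy 2.4.6 solved the reads, and Matplotlib 3.10.9 drew the figures.

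The text names HRAS, the 10 genes with the largest change in each direction for each H-Ras comparison, and 5 for the interaction and for the vector lines. These were taken among called genes with a symbol and a mean of at least 100 in the higher group (in any group for the interaction), with no overlap of the groups except in the interaction. From each fixed list up to 4 members with the smallest adjusted p could be named, with those that moved against the rest. Some genes that this rule gives are not reported here. EPCAM and TP63 in the p53-deleted comparison fall outside this rule and were chosen after their values were seen, as were KRT5 and TGFBI in the p53 wild-type comparison and the authors' deposited means of these 2 genes, FN1 and SLC7A5. The authors' deposited values of ELF3, MUC1, AKR1C1, AKR1C2 and AKR1C3 were also chosen after seeing the data. The 20 lists were MAPK output and feedback, EGF family ligands, p53 target genes, CDK inhibitors, secreted inflammatory factors, matrix proteases and inhibitors, cell cycle and DNA replication, mesenchymal, epithelial junction, basal and hemidesmosome, luminal, squamous differentiation, glycolysis, interferon response, cholesterol synthesis and uptake, antioxidant (NRF2), amino acid and ER stress, and fibroblast, leukocyte and endothelial markers. They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 20 lists, with an estimated correlation and with fry beside it. With the estimated correlation 0 list calls held in any of the 4 comparisons. A fold against a group with 0 reads used a floor of 3 reads over the group, and ratios with 1 to 3 reads have exact binomial 95% intervals, which cover counting error only.

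The test was also run on simulated data, after the first fits to the real values. Negative binomial counts were drawn for the tested genes from their means over the libraries of the fit. All genes had the same dispersion, the median over genes, and no library stood apart. The rates below therefore do not cover genes of differing dispersion or libraries that stand apart. In each simulation 200 genes were changed 1.5, 2, 4 or 8-fold. The test recovered 50%, 92%, 100% and 96% of them, in that order, for the p53 wild-type comparison with 18 false calls (9.63% of calls) over 12300 genes. For the p53-deleted comparison it recovered 78%, 90%, 100% and 96% with 3 false calls (1.62% of calls) over 12612 genes. It recovered, for the interaction, 20%, 74%, 86% and 98% with 6 false calls (4.14% of calls) over 12925 genes. For the vector lines it recovered 58%, 92%, 98% and 98% with 10 false calls (5.46% of calls) over 12336 genes. Of 10 lists of 20 genes with 10 members raised 1.5-fold, 10 were called in each comparison by camera and by fry. Of 10 unshifted lists camera called 0, 0, 0 and 1 in the same order of comparisons, and fry called 0. The simulated genes were drawn independently and the lists at random. These counts therefore do not give the rate of false list calls for correlated genes. The estimated correlation of the real cell cycle list was 0.94 in the p53 wild-type comparison.

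Alternatives were upper-quartile and TMM scaling, pseudocounts of 0.1 and 10, no filter and a filter of 10 CPM, stricter thresholds, all 12 libraries in 1 fit, and leaving out each library. The authors' own calls, TMM scaling, and leaving out p53 wild-type vector A and H-Ras C together were added after seeing the data, and these 2 libraries were singled out from the principal components and the chi-square values. CDKN2A, CDKN2B and other genes with no reads were not tested.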

Results

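RNA sequencing was carried out on MCF10A, an established, non-tumorigenic line of human mammary epithelial cells, in 4 groups of 3 libraries. The p53 wild-type groups carried either the empty pBabepuro vector or a stably expressed H-Ras mutant (H-RasV12) delivered by retrovirus, and the p53-deleted groups carried the same constructs in cells labelled as p53-deleted. The control of each H-Ras line was the vector line made together with it, so p53 status was confounded with the pair of lines. Each H-Ras line was compared with a single vector line, so H-Ras cannot be told apart from other differences between those lines. Values were normalized gene counts, with estimated totals of 7846960 to 10075600 reads per library. Mitochondrial genes held 2.62% to 3.14% of the group mean totals. Within each group the libraries were named A, B and C by falling size factor and carried no replicate number. Errors are SD over n = 3 libraries for levels and SE for log2 fold changes, and each adjusted p is from limma with Benjamini-Hochberg adjustment. The labels do not say that the replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

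HRAS (ENSG00000174775), which encodes the small GTPase H-Ras, rose from 859.9 ± 125 to 16949 ± 1903 normalized counts in the p53 wild-type H-Ras line and from 839.7 ± 42.8 to 17779 ± 1140.2 in the p53-deleted H-Ras line. Its log2 fold changes were 4.304 ± 0.14 (adjusted p = 5.2e-06) and 4.40 ± 0.08 (adjusted p = 2.0e-11), and their difference, 0.10 ± 0.17, did not pass the test (adjusted p = 0.73). Gene counts cannot separate the introduced transcript from the endogenous gene.

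**Figure D1:**
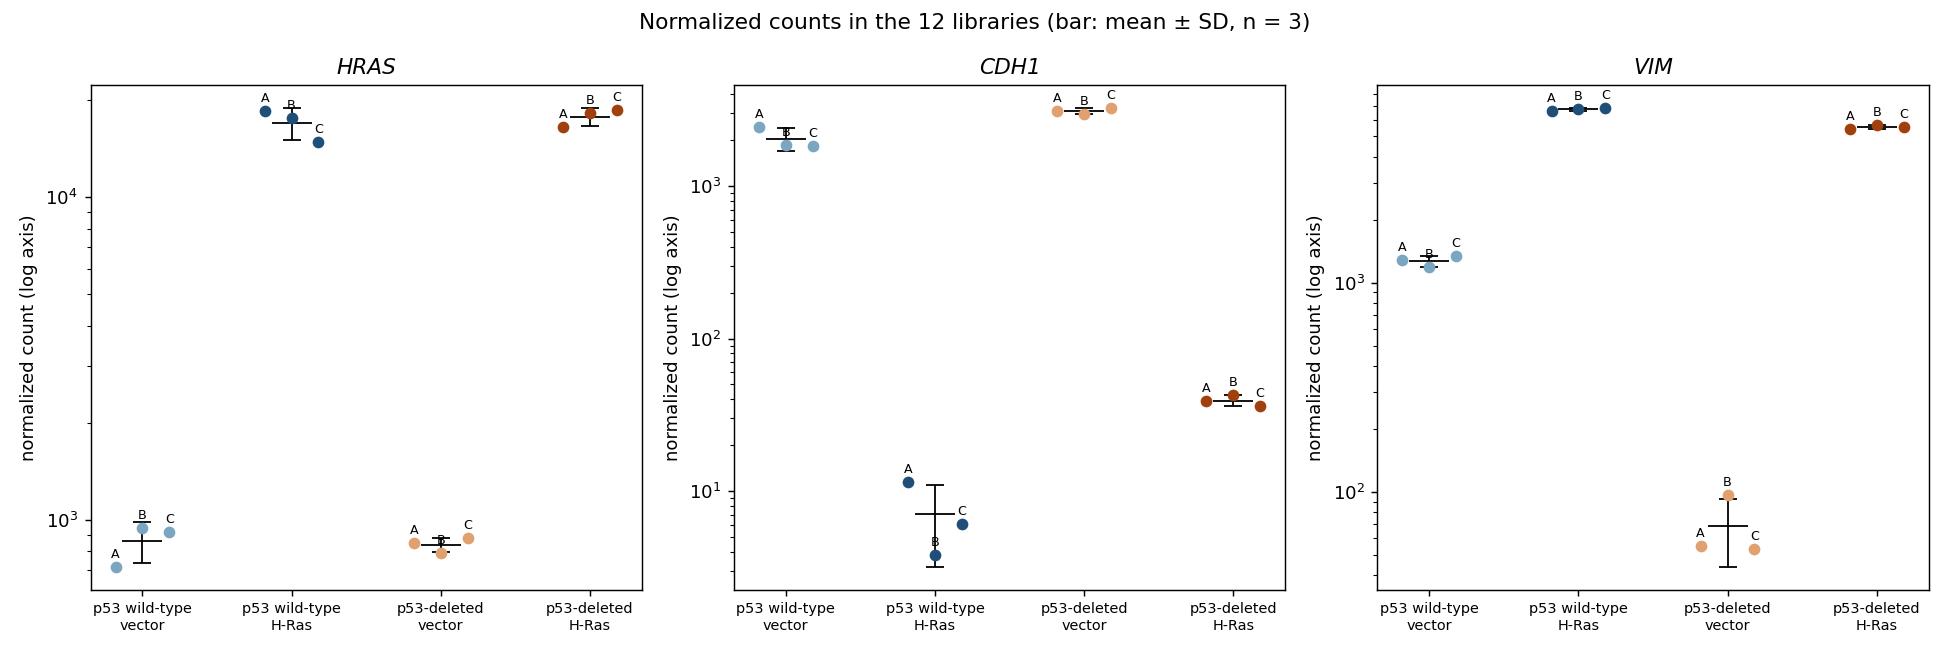
Normalized counts of HRAS, CDH1 and VIM on log axes in the 12 libraries, with points for libraries A to C of each group and bars for the mean ± SD (n = 3). HRAS lies at 717 to 946 in the 6 vector libraries and at 14809.5 to 18592 in the 6 H-Ras libraries, which also lie above the vector libraries for VIM and below them for CDH1. Another solution of the HRAS mean would put the p53 wild-type H-Ras libraries at 28767, 13304 and 8776.

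The libraries separated by H-Ras along the first principal component, which held 45.3% of the variance over 13254 genes, and by p53 background along the second, with 35.4%. Within the p53 wild-type background, vector library A and H-Ras library C stood apart from the others of their groups. Chi-square per degree of freedom was 24.2 and 29.6 between vector A and the other vector libraries, against 4.33 between B and C. For H-Ras C it was 27.7 and 30.03, against 2.52 between A and B, and in the p53-deleted groups it ranged from 2.29 to 12.4. No pair of libraries agreed within sampling noise. The cell cycle list had a median log2 deviation from the group's other libraries of -0.84 in vector A and 1.602 in H-Ras C.

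**Figure D2:**
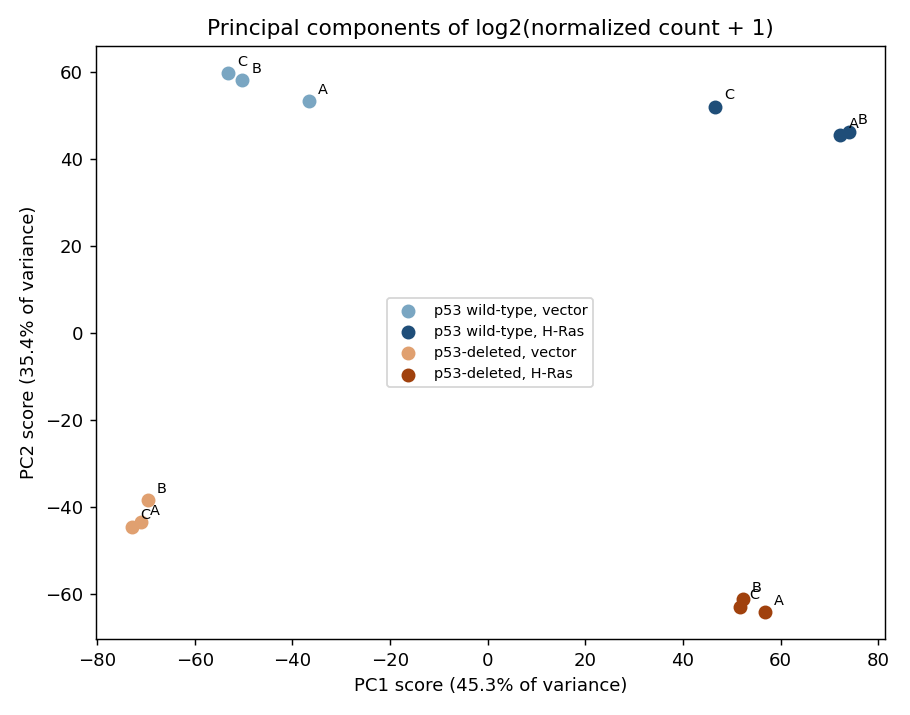
Scores of the 12 libraries on principal components 1 and 2 of log2(normalized count + 1), with the percent of variance on each axis and the library letter beside each point. The H-Ras libraries lie on the right and the vector libraries on the left, and the p53 wild-type libraries lie above the p53-deleted libraries.

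The first comparison asked what H-Ras changed in p53 wild-type MCF10A cells. Members of the epithelial junction list were among the genes that fell most. CDH1, which encodes E-cadherin, fell from 2041 ± 349 to 7.11 ± 3.92 normalized counts (log2 fold change -8.07 ± 0.34, adjusted p = 1.0e-05), and TP63, a transcription factor of basal epithelial cells, fell from 1049 ± 165 to 1.97 ± 1.71 (-8.70 ± 0.52, adjusted p = 4.6e-05). The epithelial regulators ESRP1 and ELF3 fell from 1386 ± 243 to 3.52 ± 2.37 and from 774 ± 383 to 1.95 ± 0.0645. LAD1, RAB25 and SYT8 had log2 fold changes of -8.18, -7.90 and -7.92. PHACTR3, with 0 reads in the H-Ras libraries, was at least 230.0-fold lower, against a floor of 3 reads over the group. The ratio of vector to H-Ras level was 723 (95% interval 199.6 to 5972, 2 against 1399 reads) for AP1M2, a subunit of an epithelial clathrin adaptor, and 457 (95% interval 156 to 2218, 3 against 1327 reads) for GRHL2, an epithelial transcription factor.

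Among the genes that rose most in p53 wild-type cells, C3AR1, the receptor for complement C3a, went from 5.87 ± 5.76 to 603 ± 207 normalized counts (log2 fold change 6.77 ± 0.63, adjusted p = 3.2e-04). C5AR2, a receptor for complement C5a, rose from 7.95 ± 3.19 to 911 ± 582, and FPR1, a formyl peptide receptor, from 4.25 ± 1.75 to 414 ± 216. COL6A3, a chain of collagen VI, rose from 10.4 ± 0.856 to 875 ± 231 (6.23 ± 0.23, adjusted p = 6.3e-06). The proteoglycan gene SRGN and the microtubule-associated gene MAP1B rose from 7.91 ± 1.54 to 461 ± 101 and from 34.9 ± 13.1 to 1978 ± 259. GPR4, RP11-153M7.3 and APCDD1L-AS1 had log2 fold changes of 5.94, 5.86 and 6.76, and for the antisense gene APCDD1L-AS1 reads of the other strand could not be told apart because the strand setting was not given. CACNG7, a calcium channel subunit, had an H-Ras to vector ratio of 119.7 (95% interval 40.7 to 583, 3 against 371 reads).

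Of the lists fixed before the data were examined, the epithelial junction list fell in p53 wild-type cells: 0 of 19 rose and 18 fell (0 and 18 adjusted over the list alone), with log2 fold changes of -8.07 for CDH1, -8.41 for ESRP1, -7.90 for RAB25 and -7.93 for GRHL2. For epithelial junction genes camera gave adjusted p = 4.2e-16, and adjusted p = 0.10 with an estimated correlation. The list's median deviation was 0.39 in vector A and -0.32 in H-Ras C, the libraries that stood apart, and without both 14 of 15 members were lower, with a median of -1.88 against -2.89. These medians cover different genes, because members expressed only in the vector line could not pass the filter in that fit. They do not show a weaker fall. Among basal and hemidesmosome genes 0 of 16 rose and 12 fell (1 and 12 adjusted over the list alone), including -8.70 for TP63, -4.31 for LAMA3, -3.59 for COL17A1 and -5.62 for KRT6B. For basal genes camera gave adjusted p = 8.2e-10, and adjusted p = 0.055 with an estimated correlation. The deviation of the basal genes was -0.26 in H-Ras C. LAMA3 and COL17A1 encode parts of the anchorage to the basement membrane, and KRT6B shares sequence with KRT6A, so reads of these 2 keratins may be split between them. For luminal genes 0 of 11 rose and 10 fell (0 and 10 adjusted over the list alone), including -7.93 for ELF3, -1.52 for KRT18 and -3.29 for FOXA1. For luminal genes camera gave adjusted p = 1.4e-08, and adjusted p = 0.055 with an estimated correlation. Without both libraries 7 of 8 luminal genes were lower, with a median of -1.23 against -3.09, again over different genes. The mesenchymal list rose: 12 of 19 rose and 1 fell (14 and 1 adjusted over the list alone). VIM, the intermediate filament vimentin, rose from 1270.0 ± 76.7 to 6731 ± 107 normalized counts, and log2 fold changes were 4.78 for ZEB2, 2.11 for TNC and 4.71 for ZEB1. For mesenchymal genes camera gave adjusted p = 2.7e-08, and adjusted p = 0.09 with an estimated correlation. TGFB2, a ligand of the TGF-beta family, fell against the rest of that list (-0.99). Among squamous differentiation genes 2 of 9 rose and 5 fell (2 and 5 adjusted over the list alone). The squamous list was not called by camera (adjusted p = 0.085) and was called lower by fry (adjusted p = 2.0e-04). Without both libraries it gave 2 higher and 1 lower of 4, with a median of 0.61 against -3.07. In that fit, chosen after seeing the data, genes expressed only in the vector line cannot reach 10 normalized counts in 3 libraries, so fewer were tested. SPRR1B, a cornified envelope gene, had 0 reads with H-Ras and was at least 73.3-fold lower. SBSN and S100A8 rose (1.72 and 1.54). The call for S100A8 was lost when libraries were left out, with adjusted p = 0.14 without vector B, 0.14 without vector C, 0.13 without H-Ras A and 0.14 without H-Ras B, within a range of 2.7e-11 to 0.14 over the alternatives.

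Genes for secreted inflammatory factors rose with H-Ras in p53 wild-type cells: 11 of 15 rose and 0 fell (12 and 0 adjusted over the list alone). CXCL3 rose from 33.3 ± 6.05 to 1364 ± 108, CSF3, a granulocyte growth factor, from 86.2 ± 13.0 to 2860.1 ± 112 and CXCL1, a neutrophil attractant, from 1131 ± 159 to 8686 ± 528 normalized counts. For secreted factors camera gave adjusted p = 8.2e-10, and adjusted p = 0.15 with an estimated correlation. Among matrix proteases and their inhibitors 9 of 15 rose and 3 fell (10 and 4 adjusted over the list alone). Log2 fold changes were 3.36 for SERPINE2 and 1.47 for PLAUR, and TIMP3, PLAU and PLAT fell (-3.14, -0.51 and -0.82). PLAU lost its call in other fits, with adjusted p = 0.06 without vector C, 0.088 without H-Ras A, 0.10 without H-Ras B and 0.089 in a fit of all 12 libraries, within a range of 0.001 to 0.10 over the alternatives. For matrix proteases camera gave adjusted p = 0.0045, and adjusted p = 0.34 with an estimated correlation. SERPINE2 encodes a protease inhibitor, and PLAU and PLAT the urokinase and tissue plasminogen activators. For MAPK output and feedback genes 10 of 17 rose and 1 fell (10 and 1 adjusted over the list alone), including the pathway inhibitors DUSP4, SPRY4 and SPRED1 at 1.41, 2.19 and 1.47 and MYC at -0.76. For MAPK output genes camera gave adjusted p = 3.4e-04, and adjusted p = 0.28 with an estimated correlation. The median deviation of the MAPK list was 0.17 in vector A and -0.29 in H-Ras C. Among glycolysis genes 8 of 16 rose and 0 fell (8 and 0 adjusted over the list alone), including ENO2 and PGK1 at 3.45 and 0.80. For glycolysis genes camera gave adjusted p = 0.0012, and adjusted p = 0.15 with an estimated correlation. Amino acid and ER stress genes gave 7 higher and 3 lower of 20 (9 and 3 adjusted over the list alone), with VLDLR at 4.17 and the amino acid transporter subunit SLC3A2 at -1.47. For ER stress genes camera gave adjusted p = 0.033, and adjusted p = 0.52 with an estimated correlation, and fry did not call them (adjusted p = 0.15). In H-Ras C, which stood apart, the secreted factors, the proteases and the ER stress genes had median deviations of -0.61, -0.59 and -0.50. Without it and vector A the ER stress genes gave 13 higher and 3 lower of 18, an alternative chosen after seeing the data.

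Markers of other cell types were also measured in p53 wild-type cells. Of fibroblast markers 3 rose and 1 fell of 5 (3 and 1 adjusted over the list alone; camera adjusted p = 0.033), and the call was lost with adjusted p = 0.33 with an estimated correlation. They were led by COL6A3 and by DCN, the proteoglycan decorin (4.39), with COL1A1 lower (-1.54), and their median deviation was -0.56 in H-Ras C. Endothelial markers gave 2 higher of 3, also 2 adjusted over the list alone, with ROBO4 at 2.14 and KDR at 2.51. For endothelial markers camera gave adjusted p = 0.025, and adjusted p = 0.26 with an estimated correlation. Of leukocyte markers 2 rose and 1 fell of 4 (2 and 1 adjusted over the list alone; camera adjusted p = 0.29), with LAPTM5 higher (3.39) and CSF1R lower (-1.16). The call for CSF1R was lost without any 1 of the 6 libraries and in 2 other fits, with adjusted p = 0.096 without vector A, 0.11 without vector B, 0.079 without vector C, 0.12 without H-Ras A, 0.0501 without H-Ras B, 0.069 without H-Ras C, 0.066 with no filter and 0.078 without both libraries that stood apart, within a range of 0.015 to 0.12 over the alternatives. The median deviation of the leukocyte markers was 0.71 in vector A and -1.19 in H-Ras C.

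Other lists were not called by camera in p53 wild-type cells. Of p53 target genes 3 rose and 5 fell of 25 (3 and 5 adjusted over the list alone; camera adjusted p = 0.94), with the cell cycle inhibitor CDKN1A at 0.81, BTG2 at -1.29 and RRM2B at 0.90. Of EGF family ligands 3 rose and 2 fell of 7 (4 and 2 adjusted over the list alone; camera adjusted p = 0.12), with EREG higher (2.14) and HBEGF and NRG1 lower (-0.88 and -1.10). NRG1 lost its call in 1 fit, with adjusted p = 0.053 without vector B, within a range of 3.1e-05 to 0.053 over the alternatives. The antioxidant (NRF2) list gave 6 higher and 3 lower of 16 (8 and 4 adjusted over the list alone; camera adjusted p = 0.053). Among interferon response genes 4 were higher and 3 lower of 17 (4 and 4 adjusted over the list alone; camera adjusted p = 0.96). For cholesterol genes the counts were 0 and 2 of 17 (0 and 2 adjusted over the list alone; camera adjusted p = 0.89), with a median of -0.08 and a mean of 0.03. For CDK inhibitors they were 2 and 0 of 4 (2 and 1 adjusted over the list alone; camera adjusted p = 0.37), and CDKN2A and CDKN2B were listed at 0 in all 4 group means of the authors' deposited table. The cholesterol list and the NRF2 list had median deviations of 0.27 and 0.23 in vector A and -0.52 and -0.52 in H-Ras C. Without both libraries, an alternative chosen after seeing the data, the cholesterol list gave 10 higher and 2 lower of 17 with a median of 0.31, and the NRF2 list 9 higher and 4 lower of 16. The p53 target genes then gave 8 higher and 10 lower of 25, and the interferon response genes 6 higher and 6 lower of 16.

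Cell cycle and DNA replication genes gave 2 lower and 0 higher of 28 in p53 wild-type cells and 0 adjusted over the list alone (median log2 fold change -0.80, camera adjusted p = 0.0017, adjusted p = 0.62 with an estimated correlation, fry adjusted p = 0.28). MCM2 and MCM5, subunits of the replicative helicase, fell from 1924 ± 481 to 654 ± 564 and from 1481 ± 269 to 562 ± 441 normalized counts. The call for MCM2 was lost when libraries were left out, with adjusted p = 0.14 without vector B, 0.13 without vector C, 0.13 without H-Ras A and 0.13 without H-Ras B, within a range of 1.4e-11 to 0.14 over the alternatives. For MCM5 this gave adjusted p = 0.051 without vector A, 0.13 without vector B, 0.13 without vector C, 0.13 without H-Ras A and 0.13 without H-Ras B, within a range of 7.8e-12 to 0.13 over the alternatives. Vector A and H-Ras C stood apart, with a median deviation for this list of -0.84 and 1.602, and with both left out, an alternative chosen after seeing the data, 28 of 28 members were called lower, with a median of -1.68.

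**Figure D3:**
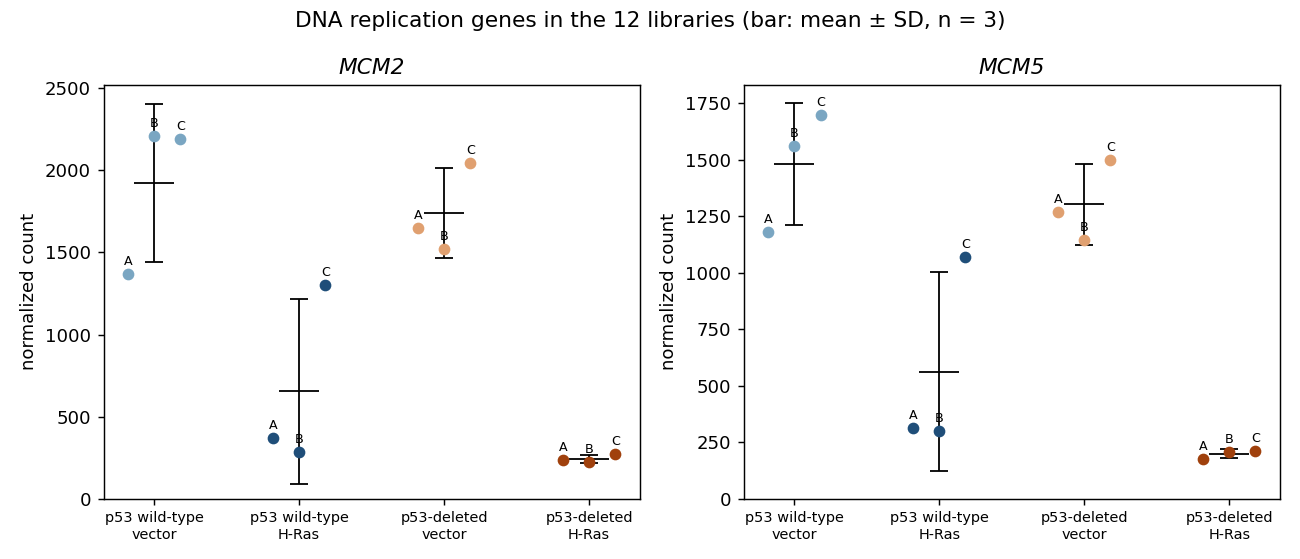
Normalized counts of MCM2 and MCM5 in the 12 libraries, with points for libraries A to C of each group and bars for the mean ± SD (n = 3). In the p53 wild-type background, vector A lies below the other vector libraries and H-Ras C above the other H-Ras libraries, and the p53-deleted H-Ras libraries lie below the p53-deleted vector libraries.

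In total 3199 of 12462 genes passed an adjusted p of 0.05 in p53 wild-type cells, 1616 higher and 1583 lower, with 1601 at an absolute log2 fold change of at least 1. The authors' deposited table called 2165 genes, of which 1985 were also called here and 0 went the opposite way. The values of the 2 groups did not overlap for 42.4% of genes, against 10% by chance. The count was 1706, 1926, 1798 and 1700 without vector B, vector C, H-Ras A and H-Ras B, and 6804 without vector A and H-Ras C together, an alternative chosen after seeing the data.

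The same question was asked in the p53-deleted lines. SRGN rose from 3.32 ± 0.526 to 3211 ± 366 normalized counts (log2 fold change 9.54 ± 0.15, adjusted p = 4.6e-12). The secreted hormone gene STC1 rose from 7.03 ± 2.31 to 2282 ± 621, and VIM from 68.4 ± 24.5 to 5531 ± 117 (6.37 ± 0.18, adjusted p = 5.8e-10). FAM65B and the potassium channel gene KCNMA1 rose from 7.38 ± 2.69 to 1932 ± 47.4 and from 1.99 ± 0.0894 to 352 ± 52.7. AKR1C1, an aldo-keto reductase whose reads may be shared with its paralogs, rose from 44.0 ± 9.30 to 3805 ± 130.5. CADM3, a cell adhesion gene with 0 reads in the vector libraries, was at least 287-fold higher, and the H-Ras to vector ratio of IL1RL1, an interleukin receptor, was 213 (95% interval 58.7 to 1767, 2 against 429 reads). CACNG8 and APCDD1L-AS1 had log2 fold changes of 6.97 and 7.46.

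Among genes falling most in the p53-deleted lines, RAB25, GRHL2 and the peptidase gene KLK10 had 0 reads with H-Ras and were at least 1238-fold, at least 929-fold and at least 532-fold lower. KRT17 fell from 3111 ± 318 to 4.96 ± 0.268 normalized counts (log2 fold change -9.02 ± 0.13, adjusted p = 4.1e-12), and KRT13, a keratin of stratified epithelia, from 1505 ± 520.5 to 2.00 ± 2.06. KRT17 has near-identical copies, so its reads may be split. FXYD3 and MIR205HG fell from 3273 ± 747 to 6.33 ± 2.56 and from 1235 ± 249 to 1.64 ± 0.535. The ratio of vector to H-Ras level was 1392 (95% interval 385 to 11501, 2 against 2768 reads) for SCEL, 1176 (95% interval 325 to 9719, 2 against 2339 reads) for ALPP and 922 (95% interval 315 to 4474, 3 against 2750 reads) for UCA1. CDH1 fell from 3102 ± 139.6 to 39.3 ± 3.27 and TP63 from 1032 ± 33.4 to 2.01 ± 1.06.

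In the p53-deleted lines the epithelial junction list fell: 0 of 20 rose and 20 fell (0 and 20 adjusted over the list alone), among them ESRP1 and EPCAM, an epithelial adhesion gene, at -6.38 and -2.85. For epithelial junction genes camera gave adjusted p = 1.2e-14, and adjusted p = 0.17 with an estimated correlation. Of basal and hemidesmosome genes 1 of 15 rose and 13 fell (1 and 14 adjusted over the list alone), with -7.78 for COL17A1, -4.90 for LAMA3 and -3.61 for KRT6A and DST, a cytoskeletal linker, higher at 0.93. For basal genes camera gave adjusted p = 3.0e-09, and adjusted p = 0.17 with an estimated correlation. Luminal genes fell as a list: 1 of 9 rose and 7 fell (1 and 7 adjusted over the list alone), with -5.86 for KRT15, -5.44 for ELF3 and -1.88 for FOXA1 and the mucin gene MUC1 higher at 1.12. For luminal genes camera gave adjusted p = 0.0047, and adjusted p = 0.32 with an estimated correlation. Squamous differentiation genes fell too: 1 of 11 rose and 7 fell (1 and 7 adjusted over the list alone). For squamous genes camera gave adjusted p = 0.0013, and adjusted p = 0.17 with an estimated correlation. SPRR1B was at least 92.5-fold lower, and the vector to H-Ras ratio of IVL, involucrin, was 291 (95% interval 80.1 to 2406, 2 against 578 reads). S100A8 rose (1.02), and its call was lost in other fits, with adjusted p = 0.13 without vector A, 0.12 without vector C, 0.18 without H-Ras B, 0.11 without H-Ras C and 0.087 in a fit of all 12 libraries, within a range of 0.0044 to 0.18 over the alternatives. The mesenchymal list rose: 11 of 18 rose and 2 fell (12 and 2 adjusted over the list alone), with 6.37 for VIM, 2.99 for ITGA5 and 6.30 for ZEB1. For mesenchymal genes camera gave adjusted p = 2.4e-04, and adjusted p = 0.17 with an estimated correlation. SNAI2, a transcription factor, and AXL, a receptor kinase, fell in it (-1.58 and -0.30), and AXL lost its call in other fits, with adjusted p = 0.072 without H-Ras B and 0.11 in a fit of all 12 libraries, within a range of 0.0082 to 0.11 over the alternatives.

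Cell cycle and DNA replication genes fell with H-Ras in the p53-deleted lines: 0 of 28 rose and 28 fell (0 and 28 adjusted over the list alone), with a median log2 fold change of -2.24. For cell cycle genes camera gave adjusted p = 3.1e-15, and adjusted p = 0.17 with an estimated correlation. MCM4 fell from 2701 ± 136 to 374 ± 30.5, MCM2 from 1740.2 ± 273 to 244 ± 24.7, MCM5 from 1303 ± 179 to 199 ± 19.0 and PCNA, the sliding clamp of replication, from 2531 ± 169 to 535 ± 11.2 normalized counts. Among p53 target genes 13 of 25 rose and 5 fell (13 and 5 adjusted over the list alone), with PLK2, GDF15, RRM2B and CDKN1A at -4.02, 3.23, 1.32 and 1.45. The list was not called by camera (adjusted p = 0.079) and was called higher by fry (adjusted p = 0.01). For CDK inhibitors the counts were 2 higher and 2 lower of 5 (2 and 2 adjusted over the list alone; camera adjusted p = 0.88), with a median of -0.10 and a mean of 0.23.

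Secreted inflammatory factors rose with H-Ras in the p53-deleted lines: 11 of 13 rose and 1 fell (11 and 1 adjusted over the list alone). CXCL1 rose from 70.6 ± 4.90 to 401 ± 102, VEGFA, an angiogenic factor, from 384 ± 79.1 to 1495 ± 229.8 and CSF3 from 198 ± 52.1 to 1015 ± 219 normalized counts. IL1A, an interleukin gene, fell from 976 ± 179 to 194 ± 49.2. For secreted factors camera gave adjusted p = 2.4e-04, and adjusted p = 0.37 with an estimated correlation. Of matrix proteases and inhibitors 8 of 12 rose and 2 fell (8 and 2 adjusted over the list alone), with 5.29 for SERPINE2 and 3.81 for TIMP1 and TIMP3 and PLAU lower at -2.56 and -1.03. For matrix proteases camera gave adjusted p = 0.0018, and adjusted p = 0.18 with an estimated correlation. For MAPK output and feedback genes 13 of 18 rose and 1 fell (13 and 1 adjusted over the list alone), with SPRY4 and DUSP4 at 3.45 and 1.72 and EMP1 lower at -1.61. For MAPK output genes camera gave adjusted p = 3.7e-04, and adjusted p = 0.18 with an estimated correlation. Of EGF family ligands 3 rose and 4 fell of 7 (3 and 4 adjusted over the list alone; camera adjusted p = 0.62), with EREG higher (1.66) and NRG1 and TGFA lower (-2.94 and -1.38). Interferon response genes gave 5 higher and 5 lower of 17 (5 and 5 adjusted over the list alone; camera adjusted p = 0.88), with a median of -0.18 and a mean of 0.29.

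Metabolic and stress lists also rose in the p53-deleted lines. Antioxidant (NRF2) genes were led by aldo-keto reductases: 13 of 16 rose and 0 fell (13 and 0 adjusted over the list alone), with AKR1C2 and AKR1C3 at 5.49 and 3.89. For NRF2 genes camera gave adjusted p = 4.4e-06, and adjusted p = 0.18 with an estimated correlation. Of cholesterol genes 11 of 17 rose and 0 fell (11 and 0 adjusted over the list alone), with MSMO1 and STARD4 at 0.89 and 0.70. For cholesterol genes camera gave adjusted p = 0.0059, and adjusted p = 0.49 with an estimated correlation. Of glycolysis genes 12 of 17 rose and 1 fell (12 and 1 adjusted over the list alone), with ENO2 and the lactate transporter gene SLC16A3 at 2.52 and 0.97 and the glucose transporter gene SLC2A1 lower at -1.24. For glycolysis genes camera gave adjusted p = 0.0047, and adjusted p = 0.39 with an estimated correlation. For amino acid and ER stress genes 11 of 19 rose and 2 fell (11 and 2 adjusted over the list alone), with VLDLR at 2.36 and SLC3A2 lower at -2.00. For ER stress genes camera gave adjusted p = 0.036, and adjusted p = 0.18 with an estimated correlation. Endothelial markers gave 3 higher of 3, also 3 adjusted over the list alone, with ROBO4 and KDR at 2.63 and 2.66. For endothelial markers camera gave adjusted p = 0.0072, and adjusted p = 0.17 with an estimated correlation. Fibroblast markers gave 2 higher and 2 lower of 4 (2 and 2 adjusted over the list alone; camera adjusted p = 0.61), with DCN at 5.31 and FAP at -1.87. Leukocyte markers gave 2 and 1 of 3 (2 and 1 adjusted over the list alone; camera adjusted p = 0.32), with LAPTM5 at 4.38 and CSF1R at -2.64.

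In total 7163 of 12773 genes passed the threshold in the p53-deleted lines, 3542 higher and 3621 lower, with 2554 at an absolute log2 fold change of at least 1. The authors' deposited table called 6143 genes, 5842 of which were also called here and 0 in the opposite direction. The 2 groups did not overlap for 63.2% of genes, against 10% by chance.

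Many genes differed in the same direction between the H-Ras and vector lines of both backgrounds. Of 12083 genes tested in both, 1073 were called higher in both comparisons against 411 expected for independent lists, 1022 lower in both against 439, and 153 in opposite directions against 849.8. SRGN, COL6A3, VIM and APCDD1L-AS1 rose and CDH1, TP63, RAB25, GRHL2 and ESRP1 fell in both. Across genes, which are not independent replicates, the log2 fold changes had Pearson r = 0.73 and Spearman rho = 0.61, and the comparisons shared no library. The number called in the same direction, 2095, was 4340 without vector A and H-Ras C of the p53 wild-type groups.

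The next comparison asked where the response to H-Ras differed between the 2 backgrounds. Levels in the 2 backgrounds were normalized separately. A higher change means a more positive log2 fold change in the p53-deleted lines. For a gene that fell in both backgrounds it is a smaller fall, and a lower change is a larger fall. SYT12 went from 271 ± 171 to 57.6 ± 38.2 in p53 wild-type and 18.6 ± 7.76 to 564 ± 157 in p53-deleted cells, a difference in log2 fold change of 7.297 ± 0.85 (adjusted p = 1.5e-04). CAMK2B, a calcium-dependent kinase, went from 375 ± 392 to 9.999 ± 3.82 in p53 wild-type and 21.5 ± 7.18 to 144 ± 18.9 in p53-deleted cells (7.37 ± 0.76, adjusted p = 6.6e-05). The differences were 6.52 ± 0.36 for COBL and 5.85 ± 0.38 for ALDH3A1, an aldehyde dehydrogenase, while that of 5.82 ± 0.69 for NGFR rested on 2 reads in the p53 wild-type H-Ras libraries. In the other direction PI3, a secreted protease inhibitor, went from 127 ± 36.7 to 319 ± 13.1 in p53 wild-type and 649 ± 23.4 to 31.8 ± 7.38 in p53-deleted cells (-5.70 ± 0.30, adjusted p = 3.7e-07). SERPINB2 went from 25.4 ± 13.3 to 56.3 ± 7.90 in p53 wild-type and 108 ± 34.8 to 1.65 ± 0.556 in p53-deleted cells (-6.60 ± 0.54). KRT13, KRT4 and ALPP, at -7.84, -6.30 and -5.48, were near the floor of detection in p53 wild-type cells, so these values depend on the pseudocount.

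Antioxidant (NRF2) genes had larger changes with H-Ras in the p53-deleted lines: 8 of 16 had a higher change and 0 a lower one (8 and 0 adjusted over the list alone), with 3.33 for AKR1C2, 1.32 for TXNRD1 and 1.31 for TKT. For NRF2 genes camera gave adjusted p = 1.0e-05, and adjusted p = 0.26 with an estimated correlation. AKR1C1, AKR1C2 and AKR1C3 started lower in the p53-deleted vector line. Their authors' deposited vector means were 44.0, 77.1 and 150 there, against 184, 375 and 582 in p53 wild-type cells. With H-Ras they were 3805, 3493 and 2227 against 2597, 1726 and 1785. In the p53 wild-type libraries that stood apart, the median deviation of the NRF2 list was 0.23 in vector A and -0.52 in H-Ras C. Of p53 target genes 7 of 25 had a higher change and 2 a lower one (10 and 3 adjusted over the list alone), with GDF15, MDM2 and BBC3 at 2.73, 0.91 and 1.34 and DDB2 and PLK2 at -1.11 and -1.40. For p53 target genes camera gave adjusted p = 0.02, and adjusted p = 0.21 with an estimated correlation. PLK2 lost its call in most other fits, with adjusted p = 0.092 without p53 wild-type vector A, 0.077 without p53 wild-type vector B, 0.062 without p53 wild-type vector C, 0.10 without p53-deleted vector A, 0.087 without p53-deleted vector B, 0.08 without p53-deleted vector C, 0.10 without p53-deleted H-Ras A, 0.064 without p53-deleted H-Ras B, 0.10 without p53-deleted H-Ras C, 0.0503 with upper-quartile scaling, 0.059 with no filter, 0.0504 with a filter of 10 CPM, 0.054 with a pseudocount of 0.1 and 0.061 with a pseudocount of 10, within a range of 0.017 to 0.10 over the alternatives. Without p53 wild-type H-Ras C its difference was -0.91. MDM2 and BBC3 encode the p53 ubiquitin ligase and a pro-apoptotic protein. For luminal genes 7 of 10 had a higher change and 1 a lower one (7 and 1 adjusted over the list alone), with 2.49 for ELF3, 2.46 for MUC1 and 0.99 for KRT18. ELF3 fell less steeply, with authors' deposited means from 774 to 1.95 in p53 wild-type and 343 to 6.99 in p53-deleted cells. Those of MUC1 went from 752 to 303 and from 131 to 283. For luminal genes camera gave adjusted p = 0.0053, and adjusted p = 0.21 with an estimated correlation. Cholesterol genes gave 2 higher and 0 lower of 17 (2 and 0 adjusted over the list alone). For cholesterol genes camera gave adjusted p = 0.028, and adjusted p = 0.78 with an estimated correlation, and fry did not call them (adjusted p = 0.39). The median deviation of the cholesterol list was 0.27 in vector A and -0.52 in H-Ras C of the p53 wild-type groups. Without both libraries, an alternative chosen after seeing the data, it gave 2 higher and 2 lower of 17, with a median difference of 0.08 against 0.25.

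Other lists had lower, that is more negative, log2 changes in the p53-deleted lines. Of EGF family ligands 1 of 7 had a higher change and 4 a lower one (1 and 5 adjusted over the list alone), with TGFA and EPGN at -1.46 and -2.83 and HBEGF at 2.01. For EGF family ligands camera gave adjusted p = 0.0053, and adjusted p = 0.21 with an estimated correlation. Of secreted inflammatory factors 3 of 16 had a higher change and 7 a lower one (5 and 7 adjusted over the list alone), with -2.60 for CXCL3, -2.68 for CSF3 and -2.71 for IL1A and VEGFA at 1.24. For secreted factors camera gave adjusted p = 0.04, and adjusted p = 0.68 with an estimated correlation. Their median deviation was -0.61 in p53 wild-type H-Ras C. VEGFA lost its call when libraries were left out, with adjusted p = 0.07 without p53-deleted vector A, 0.067 without p53-deleted vector C, 0.075 without p53-deleted H-Ras A and 0.057 without p53-deleted H-Ras C, within a range of 0.0095 to 0.075 over the alternatives. Among basal and hemidesmosome genes 3 of 15 had a higher change and 7 a lower one (3 and 9 adjusted over the list alone), with COL17A1 at -4.20 and P-cadherin, CDH3, at 1.61. For basal genes camera gave adjusted p = 0.0053, and adjusted p = 0.21 with an estimated correlation. Squamous genes gave 0 higher and 4 lower of 12 (0 and 4 adjusted over the list alone). For squamous genes camera gave adjusted p = 0.014, and adjusted p = 0.21 with an estimated correlation. The median difference of the squamous genes was -0.48, and -1.28 without both libraries that stood apart, with 0 higher and 5 lower of 12. For cell cycle genes 0 of 28 had a higher change and 2 a lower one (0 and 14 adjusted over the list alone). Their median log2 fold change was -0.80 in p53 wild-type and -2.24 in p53-deleted cells, so the lower change is a larger fall. For cell cycle genes camera gave adjusted p = 3.1e-06, and adjusted p = 0.59 with an estimated correlation, and fry did not call them (adjusted p = 0.16). The median difference was -1.36, and without both libraries that stood apart, an alternative chosen after seeing the data, it was -0.49 with 0 higher and 4 lower of 28. This list deviated by -0.84 in vector A and 1.602 in H-Ras C of the p53 wild-type groups. The members called with all libraries were CDK1 and BUB1, genes of mitosis, at -1.59 and -1.76. Without both libraries that stood apart the BUB1 difference was -0.94. For CDK1 the call was lost in most other fits, with adjusted p = 0.092 without p53 wild-type vector A, 0.059 without p53 wild-type vector B, 0.053 without p53 wild-type vector C, 0.082 without p53-deleted vector A, 0.10 without p53-deleted vector B, 0.071 without p53-deleted vector C, 0.10 without p53-deleted H-Ras A, 0.077 without p53-deleted H-Ras B, 0.078 without p53-deleted H-Ras C, 0.054 with no filter and 0.053 with a pseudocount of 0.1, within a range of 0.0054 to 0.10 over the alternatives. Its difference was -1.05 without p53 wild-type H-Ras C. BUB1 lost its call likewise, with adjusted p = 0.089 without p53 wild-type vector A, 0.053 without p53 wild-type vector B, 0.061 without p53 wild-type H-Ras C, 0.078 without p53-deleted vector A, 0.11 without p53-deleted vector B, 0.066 without p53-deleted vector C, 0.11 without p53-deleted H-Ras A, 0.061 without p53-deleted H-Ras B, 0.065 without p53-deleted H-Ras C, 0.054 with no filter, 0.054 with a pseudocount of 0.1 and 0.057 without both libraries that stood apart, within a range of 0.038 to 0.11 over the alternatives. The epithelial junction and mesenchymal lists were not called (camera adjusted p = 0.68 and 0.74), with members on both sides, among them EPCAM at 3.06 and DSG3 at -3.18, and VIM at 3.96 and SNAI2 at -2.97. The remaining lists were not called either, with camera adjusted p = 0.68 for MAPK output, 0.68 for proteases, 0.74 for CDK inhibitors, 0.68 for glycolysis, 0.74 for interferon response, 0.14 for ER stress, and 0.14, 0.75 and 0.28 for fibroblast, leukocyte and endothelial markers.

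In total the change differed for 2282 of 13254 genes, 1230 with a higher and 1052 with a lower change in the p53-deleted lines, and 1273 by at least 1 on the log2 scale. Without H-Ras C of the p53-deleted group the count was 1463, and without p53 wild-type vector A and H-Ras C together it was 2916, 1946 of them shared. Because each background was a separate pair of lines, these differences belong to the pairs of lines as much as to p53 status.

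The 2 vector lines were compared on recovered reads scaled together over the 12 libraries. CD70, a member of the TNF ligand family, was at 1039 ± 374 normalized counts in the p53 wild-type and 5.32 ± 0.674 in the p53-deleted vector line (log2 difference -7.31 ± 0.25, adjusted p = 4.7e-07). COL6A1, a chain of collagen VI, was at 2.07 ± 0.864 and 657 ± 47.4 (7.78 ± 0.25, adjusted p = 4.7e-07), and KRT13 had a log2 difference of 8.02 ± 0.41. C1QTNF1, with 0 reads in the p53-deleted vector line, was at least 134-fold lower there, and C1orf115, with 0 reads in the p53 wild-type vector line, at least 207-fold higher. The ratio of the higher to the lower line was 2961 (95% interval 819 to 24457, 2 against 5250 reads) for CASP14 and 337 (95% interval 115.04 to 1639, 3 against 897 reads) for BDH1, both lower in the p53-deleted line. For CASP14, at 1672 ± 2078 in the p53 wild-type vector line, 4411 of the reads came from vector A, which stood apart, and without it the ratio was 765 (95% interval 211 to 6327). The ratio was 1193 (95% interval 214 to 47166, 1 against 1346 reads) for GPAT2 and 679 (95% interval 188 to 5612, 2 against 1532 reads) for ADD2, higher in it. INPP5D, a phosphatase of phosphoinositide signaling, was at 1182 ± 139 and 1.93 ± 1.97 (-8.93 ± 0.48).

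Between the vector lines HRAS had a difference of -0.18 ± 0.13 (adjusted p = 0.32, and 0.031 without p53 wild-type vector A, within a range of 0.031 to 0.65 over the alternatives). Of p53 target genes 4 of 25 were higher and 6 lower (4 and 7 adjusted over the list alone) in the p53-deleted vector line. The list was not called by camera (adjusted p = 0.39) and was called lower by fry (adjusted p = 0.029). GDF15 was at 358 ± 114 in the p53 wild-type and 24.2 ± 6.57 in the p53-deleted vector line (-3.82), CDKN1A at 2292 ± 167 and 811 ± 72.5 (-1.50). RRM2B differed by -1.40, while TP53I3 was at 331 ± 28.5 and 750.4 ± 83.2 (1.17). Of secreted inflammatory factors 3 of 14 were higher and 9 lower (3 and 9 adjusted over the list alone), with CXCL1 at 1187 ± 164 and 66.3 ± 4.56 and IL8 (CXCL8) at 626 ± 167 and 22.3 ± 4.82. For secreted factors camera gave adjusted p = 0.005, and adjusted p = 0.59 with an estimated correlation. Among glycolysis genes 0 of 17 were higher and 8 lower (0 and 13 adjusted over the list alone), including LDHA and HK2 at -1.43 and -0.78. For glycolysis genes camera gave adjusted p = 4.8e-04, and adjusted p = 0.59 with an estimated correlation.

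The vector lines differed in 3789 of 12504 genes, 1887 higher and 1902 lower in the p53-deleted line, and their values did not overlap for 45.04% of genes, against 10% by chance. The count was 2212 without p53-deleted vector A. Each background was a separate pair of lines, so p53 status and line cannot be told apart.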

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

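The tests of mixed RNA, with the share they are held to, of reads shared between AKR1C genes and of splits with background means subtracted were chosen after the result was seen, as was the choice of the 2 libraries left out.

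For 2282 genes the interaction test found that the log2 change with H-Ras differed between the p53 backgrounds, and such a difference between groups was the reason to look at them again. Here a higher change is a more positive log2 change, which for genes that fell in both backgrounds is a smaller fall. These named genes had a higher change in the p53-deleted lines, with differences of 7.37 for CAMK2B, 7.297 for SYT12, 6.52 for COBL, 5.85 for ALDH3A1, 5.82 for NGFR, 5.53 for CADM3, 5.502 for FAM65B, 4.92 for INPP5D, 4.78 for STC1, 3.96 for VIM, 3.89 for CASP14, 3.85 for SRGN, 3.80 for SYT8, 3.33 for AKR1C2 and 3.15 for CD70. Further higher differences were 3.06 for EPCAM, 3.05 for CACNG8, 2.73 for GDF15, 2.70 for AKR1C1, 2.49 for ELF3, 2.46 for MUC1, 2.44 for BDH1, 2.38 for PHACTR3, 2.28 for AKR1C3, 2.04 for ESRP1, 2.01 for HBEGF, 1.93 for KCNMA1, 1.93 for SERPINE2, 1.80 for CDH1 and 1.61 for CDH3. Smaller positive differences were 1.58 for ZEB1, 1.41 for FOXA1, 1.34 for BBC3, 1.32 for TXNRD1, 1.31 for TKT, 1.26 for SPRY4, 1.24 for VEGFA, 1.13 for TIMP1, 1.02 for DST, 1.02 for PLAT, 0.99 for KRT18, 0.93 for BTG2, 0.91 for MDM2, 0.64 for CDKN1A and 0.63 for MYC.

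Lower changes in the p53-deleted lines were found for other named genes, with differences of -0.40 for PGK1, -0.50 for HK2, -0.58 for LAMA3, -0.88 for SPRED1, -1.11 for DDB2, -1.34 for SLC2A1, -1.36 for COL6A3, -1.39 for KRT6A, -1.40 for PLK2, -1.46 for TGFA, -1.48 for CSF1R, -1.59 for CDK1, -1.76 for BUB1, -1.81 for VLDLR and -1.84 for KRT15. More negative differences followed, with -1.84 for NRG1, -1.91 for GRHL2, -2.15 for FAP, -2.17 for EMP1, -2.34 for C1orf115, -2.36 for TNC, -2.36 for RAB25, -2.49 for KLK10, -2.52 for SCEL, -2.60 for CXCL3, -2.68 for CSF3, -2.71 for IL1A, -2.83 for EPGN, -2.97 for SNAI2 and -3.01 for MAP1B. Another set had -3.10 for GPAT2, -3.18 for DSG3, -3.22 for C3AR1, -3.40 for COL6A1, -3.56 for ADD2, -3.83 for IVL, -4.20 for COL17A1, -4.20 for SBSN, -4.33 for FPR1, -5.14 for UCA1, -5.48 for ALPP, -5.70 for PI3, -6.30 for KRT4, -6.60 for SERPINB2 and -7.84 for KRT13. Some group held 3 or fewer reads for ADD2, ALPP, BDH1, C1orf115, CADM3, CASP14, FPR1, GPAT2, GRHL2, IVL, KLK10, KRT4, NGFR, PHACTR3, RAB25, SCEL and UCA1, so their differences depend on the pseudocount and are no bounds.

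Of these 90 named genes, 20 lost the interaction call under some alternative. For CASP14 (3.89) it ended with adjusted p = 0.062 without p53-deleted vector C, 0.064 without p53-deleted H-Ras A and 0.061 without p53-deleted H-Ras C, within a range of 0.011 to 0.064 over the alternatives. For SYT8 (3.80) it ended with adjusted p = 0.055 with a pseudocount of 0.1, within a range of 2.9e-05 to 0.055 over the alternatives. For CACNG8 (3.05) it ended with adjusted p = 0.055 without p53 wild-type vector A, 0.075 without p53-deleted vector B, 0.067 without p53-deleted vector C, 0.07 without p53-deleted H-Ras B, 0.07 without p53-deleted H-Ras C and 0.057 without both libraries that stood apart, within a range of 0.0047 to 0.075 over the alternatives. For ZEB1 (1.58) it ended with adjusted p = 0.053 without p53-deleted vector C, 0.061 without p53-deleted H-Ras B, 0.051 without p53-deleted H-Ras C and 0.11 with a pseudocount of 10, within a range of 0.0053 to 0.11 over the alternatives. With a pseudocount of 10 the ZEB1 difference was 0.72, so its size depends on the pseudocount. For TIMP1 (1.13) it ended with adjusted p = 0.0504 without p53 wild-type vector A, 0.083 without p53 wild-type vector B, 0.081 without p53 wild-type vector C, 0.06 without p53 wild-type H-Ras C, 0.10 without p53-deleted vector A, 0.09 without p53-deleted vector C, 0.095 without p53-deleted H-Ras A, 0.057 without p53-deleted H-Ras C, 0.056 with no filter and 0.051 with a pseudocount of 0.1, within a range of 0.033 to 0.10 over the alternatives. For CDKN1A (0.64) it ended with adjusted p = 0.052 without p53-deleted vector A, within a range of 0.0098 to 0.052 over the alternatives. For PGK1 (-0.40) it ended with adjusted p = 0.056 without p53 wild-type vector A, 0.069 without p53 wild-type vector B, 0.067 without p53 wild-type H-Ras A, 0.066 without p53 wild-type H-Ras B, 0.052 without p53-deleted vector A, 0.071 without p53-deleted vector B, 0.062 without p53-deleted H-Ras A, 0.071 without p53-deleted H-Ras B, 0.077 without p53-deleted H-Ras C, 0.057 with upper-quartile scaling and 0.096 with no filter, within a range of 0.02 to 0.096 over the alternatives. For HK2 (-0.50) it ended with adjusted p = 0.053 without p53-deleted vector C and 0.064 without p53-deleted H-Ras A, within a range of 0.024 to 0.064 over the alternatives. For COL6A3 (-1.36) it ended with adjusted p = 0.052 without p53 wild-type vector B, 0.0501 without p53 wild-type H-Ras A, 0.054 without p53 wild-type H-Ras B, 0.065 without p53-deleted H-Ras B, 0.066 without p53-deleted H-Ras C and 0.30 with a pseudocount of 10, within a range of 0.0047 to 0.30 over the alternatives. The COL6A3 difference was -0.56 with a pseudocount of 10, so its size depends on the pseudocount. For CSF1R (-1.48) it ended with adjusted p = 0.092 without p53 wild-type vector B, 0.088 without p53 wild-type vector C, 0.074 without p53 wild-type H-Ras A, 0.097 without p53 wild-type H-Ras B, 0.069 without p53-deleted vector A, 0.11 without p53-deleted vector B, 0.061 without p53-deleted vector C, 0.10 without p53-deleted H-Ras B, 0.10 without p53-deleted H-Ras C, 0.097 with no filter, 0.051 with a pseudocount of 0.1 and 0.058 with a pseudocount of 10, within a range of 0.0067 to 0.11 over the alternatives. For KRT15 (-1.84) it ended with adjusted p = 0.091 without p53 wild-type vector B, 0.092 without p53 wild-type vector C, 0.086 without p53 wild-type H-Ras A, 0.093 without p53 wild-type H-Ras B, 0.11 without p53-deleted vector A, 0.10 without p53-deleted vector C, 0.1 without p53-deleted H-Ras A, 0.091 without p53-deleted H-Ras B, 0.059 without p53-deleted H-Ras C, 0.052 with no filter and 0.052 with a pseudocount of 0.1, within a range of 9.8e-04 to 0.11 over the alternatives. For C1orf115 (-2.34) it ended with adjusted p = 0.66 with a pseudocount of 10, within a range of 1.2e-05 to 0.66 over the alternatives. For SCEL (-2.52) it ended with adjusted p = 0.051 without p53-deleted vector A and 0.33 with a pseudocount of 0.1, within a range of 1.9e-04 to 0.33 over the alternatives. For C3AR1 (-3.22) it ended with adjusted p = 0.055 with a pseudocount of 0.1, within a range of 7.7e-05 to 0.055 over the alternatives. For IVL (-3.83) it ended with adjusted p = 0.16 with a pseudocount of 0.1, within a range of 1.7e-04 to 0.16 over the alternatives. For FPR1 (-4.33) it ended with adjusted p = 0.15 with a pseudocount of 0.1, within a range of 6.6e-05 to 0.15 over the alternatives. The ranges of adjusted p over the alternatives were 0.0095 to 0.075 for VEGFA (1.24), 0.017 to 0.10 for PLK2 (-1.40), 0.0054 to 0.10 for CDK1 (-1.59) and 0.038 to 0.11 for BUB1 (-1.76).

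Other splits of the libraries were counted. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In the p53 wild-type comparison 1 split, the real one, gave as many as its 3199 genes, and the highest other gave 613. In the p53-deleted comparison it was 1 split with 7163 genes, highest other 0, and for the vector lines 1 with 3789, highest other 0. For the interaction 2 of 100 drawn splits gave at least the real 2282 genes. These splits mix 2 lines that differ in 3789 genes before H-Ras, so their low share does not exclude chance. The other such split called 6249 genes, several times the real count, and it exchanged the p53 labels of the H-Ras libraries as a whole and kept those of the vector libraries. That exchange turns the contrast into the difference between the 2 backgrounds over their vector and H-Ras libraries, so it counts genes that differ between the pairs of lines. Each gene's mean over the 6 libraries of its background was then subtracted. Of the same 100 splits 1, the real one, gave as many as 2282 genes, and the highest other gave 2. A real interaction adds to the spread in the other splits, which lowers their counts. The test shows only that the real grouping of these libraries stood out among those drawn. Each group was a single line whose libraries may be technical, so chance between lines was not tested and is not excluded. The subtraction itself sets the split with 6249 genes to a contrast of 0, so that split carries no weight in this test.

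The first pattern is that p53 wild-type vector A and H-Ras C stood apart. Genes high in the other group and low in their own reached a median of 0.0159% of the other group's level in H-Ras C, over 39 genes, which argues against admixed vector-line RNA there. In vector A the median was 1.13% and the 75th percentile 2.16% over 10 genes, against the 62.7% of H-Ras RNA that its cell cycle deviation would need, and its epithelial junction list was higher (0.39), which argues against admixture as the cause, while a share of a few percent stays open. Length and GC content accounted for at most 4.57% of the variance of the deviations, which argues against them as the cause. The cell cycle list deviated by 1.602 in H-Ras C and -0.84 in vector A, beyond 10000 random lists in both. Random lists lack the correlation between members of this list. The cholesterol, ER stress and protease lists, at -0.52, -0.50 and -0.59, also lay beyond their random lists in H-Ras C. A different growth state of the cells is therefore only a hypothesis that this test does not single out, and a sequencing batch could not be tested.

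The second pattern is that cell cycle genes fell in the p53-deleted lines (28 of 28 called lower), against 2 of 28 in the p53 wild-type lines. Without the 2 libraries that stood apart 28 of 28 were called lower in p53 wild-type cells, so the spread of those libraries may account for the missing calls. This test is partly circular, since the same libraries deviate in this list and leaving them out removes the weakest contrast. The interaction then called 4 members lower with a median of -0.49, and a biological difference between the backgrounds stays open, as p53 status is confounded with the pair of lines.

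The third pattern is the higher change of NRF2 genes in the p53-deleted lines. Without AKR1C1, AKR1C2, AKR1C3 and AKR1B10 the median difference of the other 12 members was 0.28, with 4 called higher and 0 lower, between the bounds set. Leaving these genes out cannot test sharing among them. In the authors' deposited table AKR1C1, AKR1C2 and AKR1C3 rose 14.1, 4.60 and 3.06-fold in p53 wild-type and 86.4, 45.3 and 14.8-fold in p53-deleted cells. The fold of their total was therefore also larger in p53-deleted cells. Reads moved among them leave that total unchanged, which argues against such sharing as the source of their difference. Sharing with other genes was not tested. Without the 2 libraries that stood apart 8 members were called higher and 1 lower, with a median difference of 0.60 against 0.76. This argues against their spread as the only cause, though it may add to the difference. The 0.28 of the 12 members was computed with both libraries kept. Between the vector lines 2 members were higher and 6 lower of 16 in the p53-deleted line. How much of the higher change rests on that lower start was not tested. A biological difference tied to p53 or to the lines was not tested and stays open.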

How the results depend on the processing

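The authors' calls, TMM scaling and the fits without p53 wild-type vector A and H-Ras C were added after seeing the data. Of the genes called in the report's fits, 0 were called with the opposite sign under any alternative run. At an adjusted p of 0.01 the counts were 1694 in the p53 wild-type comparison, 924 in the interaction and 2217 between the vector lines, and at an absolute log2 fold change of at least 1 they were 1601, 1273 and 1474, with 2554 in the p53-deleted comparison and 885 genes called the same way in both, lower because these thresholds are stricter. All 12 libraries in a single fit gave 4837 in the p53 wild-type comparison; the cause was not tested. The fit without both libraries that stood apart gave 6804 there, 2781 of them among the 3199, and 4340 called the same way in both backgrounds, against 1345 from the authors' calls; the causes were not tested. Leaving out 1 library at a time gave 1700 to 4125 genes in the p53 wild-type comparison, 5844 to 6871 in the p53-deleted one, 1463 to 2217 in the interaction and 2212 to 4396 between the vector lines. In these fits a gene expressed only in the reduced group cannot reach 10 normalized counts in 3 libraries and gave no value. Scaling, pseudocount and low-value filter kept the counts within 1.5 times. Of the named genes' values under alternatives, 831 of 857 kept their direction and side of the threshold in the p53 wild-type comparison, 937 of 944 in the p53-deleted one, 1601 of 1715 in the interaction and 240 of 241 between the vector lines, and 0 reversed. An estimated correlation ended the calls of 12, 14, 9 and 2 lists, in that order, and fry ended 2, 0, 2 and 0 and added 3, 5, 1 and 9. In p53 wild-type cells fry added the EGF ligand, CDK inhibitor and squamous lists. In the p53-deleted lines it added the EGF ligand, p53 target, CDK inhibitor, fibroblast and leukocyte lists, and in the interaction the fibroblast list. No paired analysis was possible because the solved libraries carry no replicate number. Count tests on raw counts were not run because the tables hold none. In the data simulated at the depths of these libraries and a common dispersion, 1.5-fold changes were often missed, most in the interaction (20% recovered). Depth was not varied, so its part was not tested.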

Other observations

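Some very abundant genes had no unique solution in a group and were not tested in the comparisons that use it. FN1 had none in either H-Ras group, and KRT5, TGFBI and SLC7A5 had none in the p53-deleted vector group and were tested with limma in p53 wild-type cells. In the authors' deposited table FN1, fibronectin, went from 3845 to 64069.7 mean normalized counts with H-Ras in p53 wild-type cells and from 21308 to 105136 in p53-deleted cells (deposited adjusted p = 3.9e-11 and 0.0072). KRT5, a basal keratin, went from 34616 to 5245 and from 45144 to 3239 in the authors' deposited table (4.5e-27 and 8.3e-140). For TGFBI, a matrix protein, the authors' deposited table gave means from 12669 to 23918 in p53 wild-type and from 30954 to 23031 in p53-deleted cells (0.0011 and 0.041), opposite directions whose difference was not tested. SLC7A5, an amino acid transporter gene, went from 13226 to 2155 and from 24502 to 3944 in the authors' deposited table (2.7e-07 and 2.1e-40). In the fits run here, the log2 fold changes in p53 wild-type cells were -2.74 ± 0.15 for KRT5 (adjusted p = 3.2e-05), 0.92 ± 0.09 for TGFBI (adjusted p = 4.4e-04) and -2.58 ± 0.23 for SLC7A5 (adjusted p = 2.8e-04). FN1 was higher in the p53-deleted than in the p53 wild-type vector line, by 2.34 ± 0.19 (adjusted p = 3.6e-05).

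Most fixed lists were not called by camera between the 2 vector lines, though members differed and fry added 9 list calls. Of mesenchymal genes 4 were higher and 8 lower of 18 in the p53-deleted vector line (4 and 9 adjusted over the list alone; camera adjusted p = 0.23). VIM was at 1333 ± 81.0 normalized counts in the p53 wild-type and 64.3 ± 23.0 in the p53-deleted vector line (-4.41 ± 0.21, adjusted p = 2.8e-06). Of matrix proteases 2 were higher and 7 lower of 12 (2 and 7 adjusted over the list alone; camera adjusted p = 0.089). Luminal genes gave 0 and 6 of 10 (0 and 6 adjusted over the list alone; camera adjusted p = 0.075). NRF2 genes gave 2 and 6 of 16 (3 and 7 adjusted over the list alone, camera adjusted p = 0.25). The NRF2 list was called lower by fry (adjusted p = 0.036). Interferon response genes gave 1 and 7 of 16 (2 and 8 adjusted over the list alone; camera adjusted p = 0.16), and cell cycle genes 6 and 0 of 28 (6 and 0 adjusted over the list alone; camera adjusted p = 0.15). The median difference of the cell cycle genes was 0.29. In p53 wild-type vector A, which stood apart, their median deviation was -0.84, and how much of the difference rests on that library was not tested.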
